A study of Mus musculus with 60 samples.

How the data were processed

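The values are raw read counts per gene, deposited by the authors in a single table for all 60 libraries. Per the submitters' processing notes, reads were checked with FastQC 0.119.9, aligned to GRCm39 with STAR 2.7.9a, handled with SAMtools and Picard 2.42.2, and counted with featureCounts 2.0.1 of Subread. RNA was extracted with kits from Qiagen or Zymo, and the labels do not say which kit served which library, nor whether counting was strand-specific, so reads of overlapping or antisense genes and of pseudogenes are not separated. Genes carry Ensembl identifiers, and their names and chromosomal order were taken from GENCODE mouse release M21, which named 52081 of them, holding 99.6% of the counts. That release describes another genome build than the files, so no coordinates are given. Within each of the 10 groups no 2 libraries were duplicates of each other: the smallest chi-square per degree of freedom between a pair of the same group was 6.88, over genes with at least 20 counts. All 60 libraries came from animals of 1 sex by the transcripts of Xist and Y-linked genes.

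The comparisons, their tests, the gene lists, the rule for named genes and the alternative settings were chosen before the data were examined. Within each comparison the libraries concerned were fitted with edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, libraries were scaled by TMM, and a robust quasi-likelihood F test was used, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The library set was a term at 0 h, at 24 h and across time, where more than 1 set was present, but not with anti-IL-2. Log2 levels for lists used a prior count of 2. Errors of log2 differences are standard errors, and errors of levels are standard deviations between libraries.

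There were 14 comparisons: wild type against knockout at 0, 2, 6 and 24 h and at 24 h with anti-IL-2, anti-IL-2 within each genotype, 2, 6 and 24 h against 0 h in wild type, and 4 interactions. The 30 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 where at least 5 members were tested, adjusted over the lists of a comparison, and beside it with an estimated correlation and with fry. They comprise IL-2 and STAT5 targets, common gamma chain cytokine receptors and JAK-STAT, TCR immediate early genes, CD8 effector genes, memory-phenotype CD8 T cells, naive and quiescent T cells, inhibitory receptors and exhaustion, type I interferon-stimulated genes, interferon gamma response, S phase, G2 and M phase, MYC targets and ribosome biogenesis, glycolysis, cholesterol and SREBP targets, amino acid stress and ATF4 targets, apoptosis and survival, p53 targets, RNA quality, heat shock and handling stress, and the neighbours of Sh2b3 on chromosome 5. The remaining 10 lists are markers of B cells, monocytes and macrophages, neutrophils, dendritic cells and MHC class II, NK cells, CD4 and regulatory T cells, gamma delta T cells, erythroid cells, megakaryocytes and platelets, and CD8 T cells.

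Genes were named by the following rule. Sh2b3 is given in every group. In each genotype or anti-IL-2 comparison the 8 largest rises and 8 largest falls are named among called genes with a mean of at least 4 CPM and 1 direction in every library set, and in time and interaction comparisons the 5 largest of each. Predicted genes, pseudogenes, antigen receptor segments, Xist and Y-linked genes are left out of that part. Up to 4 members of each list are named, called members first, by smallest adjusted p. Always named are Cish, Socs1, Socs2, Socs3, Il2ra, Il2, Myc, Bcl2, Gzmb, Ifng, Tbx21 and Eomes. Where a comparison has many named genes, the text gives those of most weight and leaves the others out.

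The alternatives were DESeq2 size factors in the same fit, no filter on low counts, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights (genotype comparisons only), no library set term, each library set alone, a change of at least 1.5-fold, and leaving out each library of a group of 4 or 5. Further settings chosen after the data were seen left out knockout replicate 10 at 0 h, left out that library together with knockout replicate 3 at 2 and at 6 h, or used library numbers 10 apart as a replicate block. For each comparison up to 100 other splits of the samples were refitted.

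Calling was tried on simulated counts with the depth and spread of each comparison, in which 100 genes changed by 1 log2 unit and 100 by 2. The share recovered for genotype was 93 and 99% at 0 h, 81 and 96% at 2 h, and 66 and 94% at 6 h. At 24 h it was 72 and 84%, and 80 and 84% with anti-IL-2. It was 68% and 86% for anti-IL-2 in wild type, 62% and 86% in the knockout, and 36% and 77% for their interaction. For 2, 6 and 24 h against 0 h it was 75 and 96%, 78 and 97%, and 76 and 93%. For genotype by time it was 65 and 90%, 61 and 89%, and 58 and 86%. False calls numbered 2 to 11 per comparison. Tables were handled with the data.table package (1.17.8) and figures drawn with matplotlib 3.10.9.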

Results

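Messenger RNA was sequenced from CD8 T cells of NOD mice, a strain that develops autoimmune diabetes. The cells carried OT-I, a transgenic T cell receptor specific for an ovalbumin peptide, and naive cells were isolated from spleen by negative selection. The mice were wild type or lacked Sh2b3, the gene for an adaptor protein of cytokine receptor and JAK signalling. Cells were collected without stimulation (0 h) or after 2, 6 or 24 h on plate-bound anti-CD3 (10 µg/mL) with soluble anti-CD28 (5 µg/mL). A further 24 h culture of each genotype also contained an antibody that blocks IL-2 (10 µg/mL). The 60 libraries form 10 groups, with 11 libraries of each genotype at 0 h, 5 of each at 2, 6 and 24 h, and 4 of each at 24 h with anti-IL-2. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between samples.

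The deposited values are raw counts for 55414 genes, of which 21145 had no reads in any library. Total counts per library ran from 13987029 to 35476519, with a median of 17994613. All levels below are in CPM, the count of a gene scaled to library totals after TMM normalization. Group means of the total lay between 16.1 ± 1.16 M reads (SD, n = 5) in wild type at 2 h and 22.9 ± 7.24 M reads (n = 5) in knockout at 24 h. The library names carry numbers whose runs fall into 4 sets, A to D, which the labels do not describe. Set A holds 5 libraries of each genotype at 0, 2 and 6 h. Set B holds 2 of each at 0 and at 24 h, and set C holds 4 of each at 0 h and 3 of each at 24 h. Set D holds all libraries with anti-IL-2 and no others, so anti-IL-2 and library set cannot be told apart. Time separated the libraries on the first principal component of the 500 most variable genes, which held 64.4% of their variance, and the second held 16.9%.

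Sh2b3 (ENSMUSG00000042594) was lower in the knockout in every group compared. At 0 h its level was 79.4 ± 8.59 CPM (SD, n = 11) in wild type and 13.5 ± 3.12 CPM (n = 11) in the knockout. The other pairs of wild-type and knockout means were 147 ± 11.9 and 21.8 ± 5.90 CPM at 2 h and 116 ± 12.7 and 20.8 ± 5.31 CPM at 6 h. At 24 h they were 71.1 ± 6.24 and 11.3 ± 1.12 CPM (n = 5 each at all 3 times). With anti-IL-2 at 24 h they were 82.8 ± 6.79 and 17.2 ± 3.89 CPM (n = 4 each). The knockout kept 17.0%, 14.8%, 17.99%, 15.95% and 20.7% of the wild-type level in these 5 comparisons. No knockout library reached the level of any wild-type library of its time. In wild type the transcript rose at 2 h by 1.02 ± 0.14 (SE) log2 units (adjusted p = 1.7e-07) and was 0.65 ± 0.14 above 0 h at 6 h (adjusted p = 1.7e-04). The counts are per gene, so they do not show which exons the remaining knockout reads cover.

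**Figure D1:**
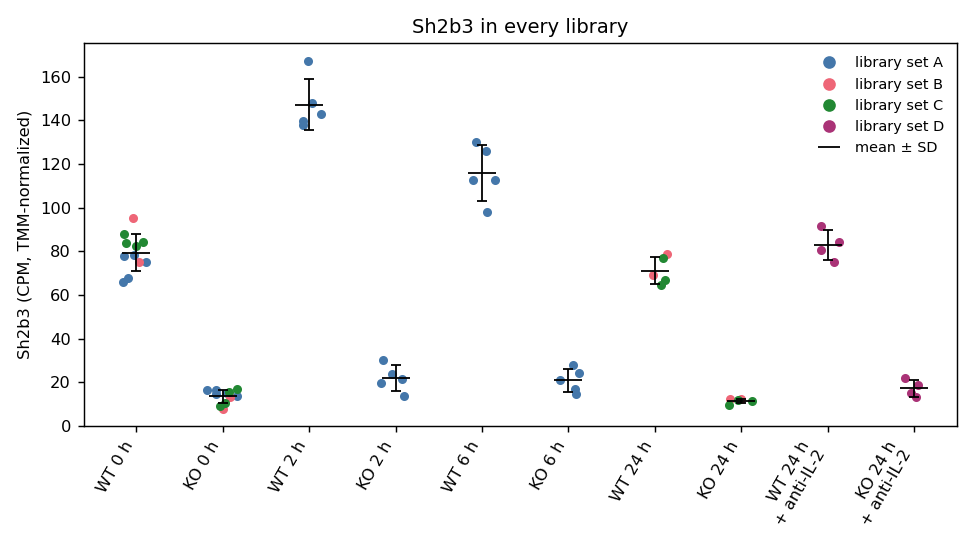
Sh2b3 in CPM (vertical axis) for each library of the 10 groups (horizontal axis), coloured by library set, with group mean ± SD. Every knockout library lies below every wild-type library of the same time, with means of 13.5 and 79.4 CPM at 0 h.

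The comparison at 0 h asks what loss of Sh2b3 changes in unstimulated, freshly isolated cells (n = 11 each, fitted with the library set as a term). Among the genes higher in the knockout were Cxcr3, by 1.35 ± 0.26 (SE) log2 units (adjusted p = 0.020), Nt5e, by 0.96 ± 0.19 (adjusted p = 0.0087), and Id2, by 0.68 ± 0.14 (adjusted p = 0.035). Id2 went from 45.3 ± 5.38 CPM (SD) in wild type to 73.4 ± 31.8 CPM. It lies in a chromosome 12 region where calls cluster, described below, so its rise may not be due to the loss of Sh2b3. Lower in the knockout were the early response genes Egr3, by −0.72 ± 0.08 log2 units (adjusted p = 1.6e-06), and Egr2, by −0.56 ± 0.12 (adjusted p = 0.016). Maf was also lower, at −0.78 ± 0.18 (adjusted p = 0.034). Each kept its direction in sets A, B and C, with Cxcr3 at 1.46, 0.86 and 1.16 and Egr3 at −0.76, −0.57 and −0.74. In all, 42 genes were higher and 39 lower in the knockout among 12802 tested, and 19 and 13 of these differed by 1.5-fold or more. Without knockout replicate 10 the count was 137.

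Other large rises at 0 h were Mid1 (1.48 ± 0.23 log2 units, SE, 0.26 in set B and 2.04 in set C), Rnf157 (1.26 ± 0.26), Sept8 (1.04 ± 0.20), Dtx4 (0.78 ± 0.13), Adi1 (0.78 ± 0.10) and Tdrd7 (0.68 ± 0.16). Other large falls were Rnf144a (−1.79 ± 0.31), Blk (−0.99 ± 0.24), Acp1 (−0.92 ± 0.10), Wfikkn2 (−0.86 ± 0.17), Fhl2 (−0.86 ± 0.14) and Vat1 (−0.55 ± 0.08). All 12 passed an adjusted p of 0.05. Tbx21 was 1.17 ± 0.28 log2 units higher (3.12 ± 1.32 to 6.96 ± 4.62 CPM, SD) and Il2ra was at −0.87 ± 0.24 (4.02 ± 0.862 to 2.26 ± 1.19 CPM), with adjusted p = 0.0583 and 0.105, neither past the threshold. Cish (0.04), Bcl2 (0.02), Myc (0.08), Socs1 (0.23), Socs3 (0.23), Gzmb (0.22), Eomes (0.28) and Ifng (0.66) did not pass either.

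Gene lists at 0 h were tested with camera against all other genes. The type I interferon-stimulated genes were higher in the knockout, with a median of 0.37 log2 units over 49 genes (adjusted p = 3.1e-30, adjusted p = 0.380 with an estimated correlation). That median was 0.77 in set B and 0.61 in set C but −0.03 in set A, where 22 of the 49 genes were above 0. Among them Rtp4 (0.43 ± 0.10), Slfn8 (0.29 ± 0.07) and Ddx58 (0.25 ± 0.06) passed over all genes tested, and 33 passed when adjusted over the list alone. The interferon gamma response had a median of 0.23 over 33 genes, with 1 called (Cd274, 0.41 ± 0.09) and 14 adjusted over the list alone (adjusted p = 3.0e-15, adjusted p = 0.380 with an estimated correlation). The G2 and M phase genes had a median of 0.44 over 30 genes, with 0 called by edgeR and 5 adjusted over the list alone (adjusted p = 2.0e-06, adjusted p = 0.380 with an estimated correlation).

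Smaller shifts at 0 h were those of the S phase genes (median 0.08, adjusted p = 0.0051), CD8 effector genes (0.21, adjusted p = 0.017) and memory-phenotype genes (0.25, adjusted p = 0.0195), each with adjusted p = 0.380 with an estimated correlation. Adjusted over the list alone, 2, 3 and 5 of their genes were higher, against 0, 1 and 2 over all genes. The effector gene called over all genes was Id2, and the memory genes were Cxcr3 and Id2. The cholesterol genes were lower (median −0.14, adjusted p = 5.0e-06, adjusted p = 0.289 with an estimated correlation), with 4 genes adjusted over the list alone and 0 over all genes by edgeR. The markers of gamma delta T cells were lower too (−0.26, adjusted p = 0.0015, adjusted p = 0.401 with an estimated correlation), with 1 gene adjusted over the list alone and 1 over all genes. Set A alone called none of these 8 lists. The S phase, effector and memory lists were not called in set B alone either, where the effector median over set means was −0.12, and without knockout replicate 10 the effector list was not called. The TCR immediate early genes, to which Egr2 and Egr3 belong, had a median of −0.00 (adjusted p = 0.291), with 2 higher and 3 lower adjusted over the list alone.

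At 2 h (n = 5 each) the comparison asks how Sh2b3 loss changes the early response to stimulation. Il2ra was lower in the knockout, at 67.5 ± 13.7 CPM (SD) against 114 ± 9.55 CPM in wild type, a difference of −0.76 ± 0.12 (SE) log2 units (adjusted p = 0.044). Ly6c1 was lower by −1.68 ± 0.29 (adjusted p = 0.044) and Trat1 by −0.89 ± 0.14 (adjusted p = 0.0498). Ubald2 was higher by 0.68 ± 0.08 (adjusted p = 0.0014), Tex2 by 0.46 ± 0.07 (adjusted p = 0.029) and Atxn2, a neighbour of Sh2b3, by 0.51 ± 0.09 (adjusted p = 0.044). With Sh2b3 and the pseudogene Gm6472 these made 8 calls, 4 in each direction, among 12372 genes. Socs3 (0.70 ± 0.21, adjusted p = 0.255), Socs1 (0.38, adjusted p = 0.352) and Tbx21 (1.59 ± 0.78, adjusted p = 0.426) were not called. Neither were Ifng (1.16), Cish (0.27), Bcl2 (0.15), Myc (−0.01), Il2 (−0.06), Gzmb (−0.10) and Eomes (−0.15). The naive and quiescent list was higher (median 0.12, 2 genes adjusted over the list alone, adjusted p = 0.0325), as was the cholesterol list (0.15, adjusted p = 0.0498). The MYC list was lower (−0.14, adjusted p = 0.0053), and each of the 3 had adjusted p = 0.851 with an estimated correlation. Over all genes edgeR called 0 of their members. The cholesterol list was called in 3 of 12 other settings (medians from 0.04 to 0.23) and was lost with DESeq2 size factors, with no filter and without any one of 7 libraries. Leaving out any one of 5 libraries ended the call of the naive list (lowest median 0.05), and leaving out knockout replicate 5 that of the MYC list. The count of calls was 3 without any one of wild-type replicates 1 to 4 or knockout replicate 1, and 5 and 4 without knockout replicates 2 and 4. It was 19 without knockout replicate 5, 45 without knockout replicate 3 and 63 without wild-type replicate 5.

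At 6 h (n = 5 each) Foxj1 was higher in the knockout by 2.27 ± 0.23 (SE) log2 units (adjusted p = 8.4e-04). The other 3 of the 4 calls among 13082 genes were Sh2b3, Gm6472 and 1700008B11Rik, a transcript near the floor that was lower, lies outside the rule for named genes and was chosen after its value was seen. The effector genes Ifng (3.33 ± 1.23, adjusted p = 0.804) and Tbx21 (1.98 ± 0.78, adjusted p = 0.824) had wide spreads in the knockout. Ifng stood at 1.39 ± 0.709 CPM (SD) in wild type and 14.3 ± 28.2 CPM in the knockout, and Tbx21 at 15.1 ± 5.60 and 60.6 ± 90.8 CPM. Socs1 was 0.83 ± 0.22 higher (adjusted p = 0.683), and Cish (1.13), Gzmb (1.30), Socs3 (0.62), Il2 (0.49), Eomes (0.38), Myc (0.02), Bcl2 (−0.04) and Il2ra (−0.27) were not called. The interferon gamma response was higher as a list, with a median of 0.81 over 33 genes (adjusted p = 6.8e-17, adjusted p = 0.666 with an estimated correlation), 0 genes called by edgeR and 25 adjusted over the list alone. Without knockout replicate 3 that median was 0.43.

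Further lists at 6 h were the type I interferon genes (median 0.30, adjusted p = 1.3e-07), CD8 effector genes (0.46, adjusted p = 0.0047), memory-phenotype genes (0.38, adjusted p = 0.0179) and common gamma chain genes (0.08, adjusted p = 0.0395), all higher and each with adjusted p = 0.666 with an estimated correlation. Lower were the p53 targets (−0.16, adjusted p = 8.9e-04), inhibitory receptors (−0.23, adjusted p = 0.0195) and markers of B cells (−0.41, adjusted p = 0.0047) and gamma delta T cells (−0.44, adjusted p = 0.0047), each also with adjusted p = 0.666 with an estimated correlation. So were the MYC genes (−0.08, adjusted p = 0.0263, adjusted p = 0.900 with an estimated correlation). edgeR called 0 members of any over all genes. Adjusted over the list alone, the memory, common gamma chain and p53 lists had 1, 2 and 2 genes, the inhibitory receptors 2 lower and 1 higher, and the other 5 had 0. Without knockout replicate 3 the effector and memory lists were no longer called, with medians of 0.08 and −0.01. The effector call also ended without wild-type or knockout replicate 2, and the memory call without wild-type replicate 4. Single libraries or the filter also ended calls of the MYC (median up to 0.06), common gamma chain, inhibitory receptor, B cell and gamma delta lists, which were called in 8, 5, 9, 10 and 11 of 12 other settings. The TCR immediate early list had a median of −0.01, a mean of 0.29 and an upward test (adjusted p = 0.870).

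After 24 h of stimulation (n = 5 each, library sets B and C fitted as a term) the comparison asks how Sh2b3 loss changes cells that have entered the effector programme. The effector regulators Id2 and Tbx21 were higher in the knockout, by 1.01 ± 0.13 (SE) log2 units (adjusted p = 0.0024) and 1.18 ± 0.21 (adjusted p = 0.024), and the cytokine gene Lta by 1.64 ± 0.26 (adjusted p = 0.0186). Id2 went from 31.8 ± 2.02 to 67.1 ± 14.6 CPM (SD), Tbx21 from 40.9 ± 26.3 to 83.3 ± 31.5 CPM and Lta from 30.8 ± 9.74 to 96.8 ± 34.0 CPM. Id2 lies in the chromosome 12 region described below, so its rise may not be due to the loss of Sh2b3. Lower in the knockout were Myb, by −0.84 ± 0.12 (adjusted p = 0.0076), and Id3, by −0.73 ± 0.12 (adjusted p = 0.019). Ikzf2 was lower by −0.73 ± 0.11 (adjusted p = 0.0156) and Tbc1d4 by −0.93 ± 0.16 (adjusted p = 0.020). In all, 29 genes were higher and 19 lower among 12906 tested, of which 25 and 15 differed by 1.5-fold or more. In sets B and C the differences were 1.41 and 0.82 for Id2, 0.53 and 1.64 for Tbx21, and 1.03 and 2.00 for Lta.

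The largest rises also included Gadd45g (2.11 ± 0.37 log2 units, SE, adjusted p = 0.024), Ifit3 (1.51 ± 0.22, adjusted p = 0.0080), Ly6c2 (1.30 ± 0.24), Gbp10 (1.22 ± 0.24), Rnf157 (1.02 ± 0.17), Iigp1 (0.89 ± 0.17) and Jun (0.79 ± 0.15). The falls were Rbpms (−2.0 ± 0.37), Tcrg-C4 (−1.18 ± 0.23), Trdc (−0.87 ± 0.10, adjusted p = 7.6e-04), Ephx1 (−0.83 ± 0.16), Timp2 (−0.79 ± 0.15) and Cdh24 (−0.69 ± 0.14). All of these passed an adjusted p of 0.05. Genes of the effector and IL-2 response with larger differences did not pass. Among them were Gzmb (3.03 ± 0.61, adjusted p = 0.120, 167 ± 160 to 960.1 ± 590 CPM, SD), Ifng (3.01 ± 0.63, adjusted p = 0.124, 17.6 ± 15.3 to 118 ± 106 CPM) and Socs2 (1.75 ± 0.46, adjusted p = 0.146). Others were Cish (1.46 ± 0.33, adjusted p = 0.109, 41.3 ± 29.5 to 96.6 ± 20.7 CPM) and Eomes (1.32 ± 0.30, adjusted p = 0.106). Il2ra was 0.63 ± 0.18 higher (adjusted p = 0.187, 305 ± 141 to 450.0 ± 78.6 CPM) and Bcl2 0.59 ± 0.15 (adjusted p = 0.122). Socs3 (0.37), Il2 (0.27), Myc (0.25) and Socs1 (0.25) were not called. The wild-type level of Cish was 73.3 ± 4.94 CPM in set B (n = 2) and 20.02 ± 5.16 CPM in set C (n = 3). Its difference was 0.35 and 2.29 log2 units. For Gzmb the differences were 1.28 and 3.97, for Ifng 1.47 and 3.67, and for Il2ra −0.02 and 1.13. Leaving out wild-type replicates 1 to 5 in turn gave 13, 20, 12, 8 and 25 calls, and leaving out knockout replicates 2 to 5 gave 24, 15, 9 and 361.

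**Figure D2:**
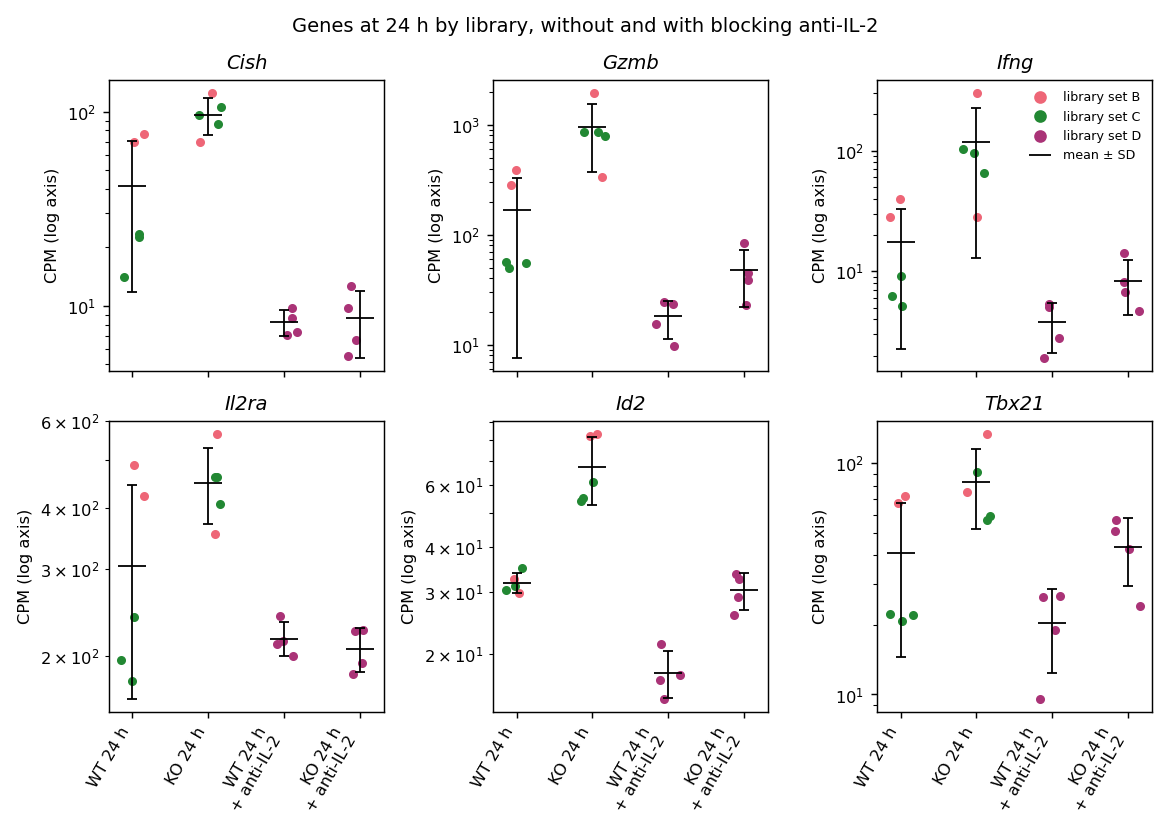
CPM on a log axis (vertical) of Cish, Gzmb, Ifng, Il2ra, Id2 and Tbx21 in each library of the 4 groups at 24 h (horizontal), coloured by library set, with group mean ± SD. Cish averages 41.3 and 96.6 CPM in untreated wild type and knockout, and 8.20 and 8.61 CPM with anti-IL-2.

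The IL-2 and STAT5 targets were higher at 24 h in the knockout as a list (median 0.31 over 36 genes, 0.14 in set B and 0.41 in set C, adjusted p = 2.1e-09, adjusted p = 0.257 with an estimated correlation). Of them 2 were called over all genes and 17 adjusted over the list alone, with 0 lower. The CD8 effector genes had a median of 0.51 (0.46 in B, 0.71 in C, adjusted p = 5.4e-08, adjusted p = 0.257 with an estimated correlation), with 2 higher over all genes (Tbx21 and Id2) and 11 higher and 1 lower adjusted over the list alone. The interferon gamma response had a median of 0.26 (0.27 in B, 0.29 in C, adjusted p = 1.4e-09, adjusted p = 0.362 with an estimated correlation). Of it 5 genes were called, among them Gbp2 (0.66 ± 0.13), Gbp5 (0.60 ± 0.11) and Igtp (0.54 ± 0.10), and 15 adjusted over the list alone. The type I interferon genes had a median of 0.29 (0.51 in B, 0.07 in C, 1 called, 9 adjusted over the list alone, adjusted p = 1.5e-04, adjusted p = 0.464 with an estimated correlation). The memory-phenotype genes had a median of 0.33 (2 called, Ly6c2 and Id2, 6 adjusted over the list alone, adjusted p = 1.2e-04, adjusted p = 0.176 with an estimated correlation).

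Growth and division lists were also higher in the knockout at 24 h. In set C, where most of these medians and those of the IL-2 and effector lists were larger, mitochondrial transcripts took 2.84 ± 0.785% (SD, n = 3) of the counts in wild type and 1.86 ± 0.0945% in the knockout. In set B they took 1.51 ± 0.149% (n = 2) and 1.28 ± 0.0331%. The G2 and M phase genes had a median of 0.43 (0.12 in B, 0.65 in C, 0 called by edgeR, 18 adjusted over the list alone, adjusted p = 4.4e-11, adjusted p = 0.362 with an estimated correlation). The MYC and ribosome biogenesis genes had one of 0.25 (0.10 in B, 0.43 in C, Gar1 called at 0.61 ± 0.10, 16 adjusted over the list alone, adjusted p = 4.4e-11, adjusted p = 0.384 with an estimated correlation). The S phase genes had a median of 0.19 (0 adjusted over the list alone, adjusted p = 0.0022, adjusted p = 0.601 with an estimated correlation). That of the glycolysis genes was 0.20 (5 adjusted over the list alone, adjusted p = 3.6e-04, adjusted p = 0.362 with an estimated correlation). The ATF4 targets stood at 0.10 (2 adjusted over the list alone, adjusted p = 0.0087, adjusted p = 0.265 with an estimated correlation). The TCR immediate early genes stood at 0.18 (1 called, 7 higher and 1 lower adjusted over the list alone, adjusted p = 0.0185, adjusted p = 0.505 with an estimated correlation) and the heat shock genes at 0.16 (1 called, 2 adjusted over the list alone, adjusted p = 0.0071, adjusted p = 0.431 with an estimated correlation).

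Lists lower in the knockout at 24 h began with the markers of gamma delta T cells (median −0.85, −1.09 in B, −0.79 in C, 2 called, 5 adjusted over the list alone, adjusted p = 5.0e-05, adjusted p = 0.257 with an estimated correlation). The naive and quiescent genes were lower (−0.18, 1 adjusted over the list alone, adjusted p = 1.2e-04, adjusted p = 0.431 with an estimated correlation). The RNA quality list of mitochondrial and nuclear transcripts was lower too (−0.47, −0.17 in B, −0.49 in C, 7 adjusted over the list alone, adjusted p = 1.5e-04, adjusted p = 0.431 with an estimated correlation). Set B alone (2 libraries of each genotype) did not call 10 of these 15 lists, and set C alone did not call the type I interferon genes. Without wild-type replicate 1 or knockout replicate 1 the S phase list was not called, with a median down to −0.04 over all settings. Any one of 4 libraries ended the call of the TCR immediate early list (median down to −0.01), and wild-type replicate 2 that of the heat shock list (down to 0.01). The effector, interferon gamma, memory and gamma delta lists were called in all 15 settings, which changed the scaling or the filter or left out a library, a set or the set term.

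The other lists were not called at 24 h. Their medians and camera adjusted p were 0.08 and 0.139 for the common gamma chain genes (4 adjusted over the list alone) and −0.10 and 0.243 for inhibitory receptors (1 called, 2 higher and 2 lower adjusted over the list alone). They were 0.07 and 0.266 for cholesterol genes, 0.05 and 0.478 for apoptosis genes (2 adjusted over the list alone), 0.03 and 0.616 for p53 targets and 0.02 and 0.344 for the neighbours of Sh2b3. Markers of B cells had −0.17 and 0.390, of monocytes and macrophages −0.02 and 0.618, and of erythroid cells 0.33 and 0.161. Those of megakaryocytes had −0.35 and 0.410 and of CD8 T cells −0.13 and 0.174. In this order 1, 0, 1, 1 and 3 genes passed adjusted over the list alone. The dendritic cell markers had a median of −0.14, a mean of 0.11 and an upward test (adjusted p = 0.616, 2 higher adjusted over the list alone). The CD4 and regulatory T cell markers had a median of 0.08, a mean of −0.06 and a downward test (adjusted p = 0.714, 1 called, 2 higher and 1 lower adjusted over the list alone). The NK cell markers had too few tested members here; with anti-IL-2 their median was −0.04, their mean −0.31 and their test upward (adjusted p = 0.814, 1 adjusted over the list alone). The neutrophil markers never had 5 tested members.

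With IL-2 blocked at 24 h (n = 4 each, set D) the comparison asks which differences between the genotypes appear without IL-2 signalling. Mid1 was higher in the knockout by 3.26 ± 0.26 (SE) log2 units (adjusted p = 4.05e-06) and the chemokine gene Ccl5 by 0.88 ± 0.16 (adjusted p = 0.023). Id2 was higher by 0.78 ± 0.14 (adjusted p = 0.020) and the interferon-induced genes Igtp by 0.56 ± 0.07 and Gbp4 by 0.55 ± 0.07 (adjusted p = 8.9e-04 each). Id2 stood at 17.7 ± 2.68 CPM (SD) in wild type and 30.2 ± 3.58 CPM in the knockout, and Igtp at 202 ± 19.9 and 294 ± 21.3 CPM. Here too the place of Id2 on chromosome 12, described below, leaves open whether its rise is due to the loss of Sh2b3. Lower in the knockout were Nr4a1, by −0.37 ± 0.06 (adjusted p = 0.013), Dusp4, by −0.43 ± 0.08 (adjusted p = 0.023), and Itm2a, by −0.49 ± 0.08 (adjusted p = 0.0094). Acp1 was lower by −1.001 ± 0.12 (adjusted p = 8.4e-04). In all, 27 genes were higher and 20 lower among 13441 tested, 13 and 5 of them by 1.5-fold or more. Cish differed by less than its spread (0.08, 8.20 ± 1.25 and 8.61 ± 3.22 CPM), as did Il2ra (−0.05, 217 ± 17.2 and 207 ± 21.5 CPM). Myc (0.02), Socs2 (−0.03) and Bcl2 (−0.08) were not called.

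Other calls with anti-IL-2 were Iigp1 (1.20 ± 0.21 log2 units, SE), Ppic (0.97 ± 0.20), Ly6a (0.92 ± 0.15), Rnf157 (0.77 ± 0.16), Plac8 (0.73 ± 0.11), Gbp6 (0.64 ± 0.10), Irgm1 (0.58 ± 0.09) and Parp14 (0.45 ± 0.09). Falls were those of Serf2 (−0.51 ± 0.09), Trappc12 (−0.51 ± 0.08), Rps7 (−0.46 ± 0.06) and mt-Tp (−0.64 ± 0.12). Gzmb (1.39 ± 0.43, adjusted p = 0.371, 18.3 ± 6.96 to 47.6 ± 25.8 CPM, SD), Ifng (1.16, adjusted p = 0.269) and Tbx21 (1.11, adjusted p = 0.308) were higher without passing. The same held for Il2 (0.89), Eomes (0.61, adjusted p = 0.108), Socs1 (0.30) and Socs3 (0.23). The interferon gamma response had a median of 0.34 (8 called, 25 adjusted over the list alone, adjusted p = 2.7e-19) and the effector genes 0.45 (2 called, Ccl5 and Id2, 11 adjusted over the list alone, adjusted p = 5.9e-07), both with adjusted p = 0.0788 with an estimated correlation. The memory genes had a median of 0.45 (3 called, Id2 among them, 8 adjusted over the list alone, adjusted p = 4.0e-06) and the type I interferon genes 0.25 (1 called, 9 adjusted over the list alone, adjusted p = 4.7e-09), both with adjusted p = 0.0788 with an estimated correlation. The inhibitory receptors were lower (−0.16, 1 called, 5 adjusted over the list alone, adjusted p = 0.0048, adjusted p = 0.0788 with an estimated correlation). The G2 and M phase genes (0.37, 11 adjusted over the list alone, adjusted p = 3.4e-11), S phase genes (0.14, adjusted p = 4.0e-06) and gamma delta markers (−0.24, 2 adjusted over the list alone, adjusted p = 0.031) had 0 genes called by edgeR. For the first, adjusted p = 0.437 with an estimated correlation, for the second, adjusted p = 0.617 with an estimated correlation, and for the third, adjusted p = 0.331 with an estimated correlation. The gamma delta list was called in 4 of 10 other settings (medians from −0.50 to −0.05), and no filter or the loss of any one of 5 libraries ended its call. Without knockout replicate 3 the inhibitory receptor list was not called. The IL-2 and STAT5 targets had a median of 0.02 (adjusted p = 0.285, 0 adjusted over the list alone). Leaving out wild-type replicates 1 to 4 in turn gave 22, 10, 17 and 28 calls, and leaving out knockout replicates 1 to 4 gave 19, 76, 24 and 18.

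Anti-IL-2 was compared with no antibody at 24 h within each genotype to show what depends on IL-2 in these cultures, with the library set as an open alternative for every difference. In the knockout Cish fell from 96.6 ± 20.7 to 8.61 ± 3.22 CPM (SD), by −3.46 ± 0.44 (SE) log2 units (adjusted p = 2.2e-04). Gzmb fell by −4.29 ± 0.76 (adjusted p = 0.0044), Ifng by −3.78 ± 0.73 (adjusted p = 0.0064) and Il2ra by −1.09 ± 0.22 (adjusted p = 0.0071) in the same comparison. In wild type Cish fell from 41.3 ± 29.5 to 8.20 ± 1.25 CPM, by −2.33 ± 0.42 (adjusted p = 0.0036), and Gzmb by −3.19 ± 0.73 (adjusted p = 0.019). Socs1 fell alike, by −1.67 ± 0.12 in wild type (adjusted p = 5.3e-08) and −1.62 ± 0.12 in the knockout (adjusted p = 8.0e-08). Falls in both were also those of Igtp (−1.12 ± 0.10 and −1.11 ± 0.10), Pim1 (−1.13 ± 0.16 and −1.59 ± 0.17), Bcl2 (−0.86 ± 0.16 and −1.51 ± 0.16) and Id2 (−0.86 ± 0.14 and −1.11 ± 0.14). Against untreated sets B and C apart, the fall of Cish was −3.15 and −1.25 in wild type and −3.49 and −3.54 in the knockout, and that of Gzmb −4.27 and −1.64 in wild type and −4.24 and −4.29 in the knockout. In wild type 410 genes rose and 467 fell among 14778 tested, and in the knockout 416 rose and 416 fell.

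Further falls in wild type were Socs2 (−3.54 ± 0.92 log2 units, SE), Coro2a (−2.28), Il12rb2 (−2.03 ± 0.57), Klf2 (−1.93 ± 0.48), Tgtp1 (−1.35 ± 0.15) and Socs3 (−1.17 ± 0.23). Rises included Adamtsl2 (2.09 ± 0.59), Klrc1 (1.99 ± 0.57), Igsf3 (1.64 ± 0.18) and Lamc1 (1.63 ± 0.19). In the knockout Socs2 (−4.81 ± 0.95), Lif (−3.96 ± 0.75), Il12rb2 (−2.46 ± 0.56), Lta (−2.23 ± 0.28) and Socs3 (−1.31 ± 0.23) fell. There Adamtsl2 (2.93 ± 0.60), Ier5l (2.45 ± 0.53), Klrc1 (2.25 ± 0.57) and Tex15 (1.97 ± 0.25) rose. Sh2b3 was 0.63 ± 0.13 higher with anti-IL-2 in the knockout (adjusted p = 0.0060) and 0.20 ± 0.13 in wild type (adjusted p = 0.402). Not called in wild type were Il2ra (−0.50 ± 0.22, adjusted p = 0.204, −1.07 against set B and 0.09 against set C), Ifng (−2.22, adjusted p = 0.0815), Tbx21 (−1.01), Eomes (−0.51), Il2 (−0.39) and Myc (0.03). In the knockout these were Tbx21 (−0.89), Eomes (−1.13), Il2 (0.33) and Myc (−0.19). In wild type leaving out untreated replicates 1, 3 and 5 gave 507, 493 and 1325 calls and leaving out anti-IL-2 replicates 1 to 4 gave 414, 433, 384 and 440. In the knockout leaving out anti-IL-2 replicates 1, 2 and 4 gave 489, 549 and 446.

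The interferon gamma response was lower with anti-IL-2 in wild type (median −0.70, 23 called, 30 adjusted over the list alone, adjusted p = 5.7e-28) and in the knockout (−0.68, 24 called, 30 adjusted over the list alone, adjusted p = 6.5e-25). The IL-2 and STAT5 targets were lower in the knockout (−0.60, 19 called, 23 adjusted over the list alone, adjusted p = 1.25e-16). These 3 calls held with an estimated correlation (adjusted p = 0.0128, 0.0197 and 0.0197). In wild type so did those of the type I interferon genes (−0.61, 15 called, 25 adjusted over the list alone), the dendritic cell and MHC class II markers (−1.26, 3 called, 6 adjusted over the list alone) and the gamma delta markers (−1.96, 5 called, 5 adjusted over the list alone), each with adjusted p = 0.0402 with an estimated correlation. Of all list calls in the 14 comparisons only these 6 and the CD8 T cell markers at 6 h against 0 h held with it. The IL-2 and STAT5 targets were also lower in wild type (−0.45, 11 called, 16 adjusted over the list alone, adjusted p = 3.2e-08). So were the memory genes (−0.49, 6 called, 8 adjusted over the list alone, adjusted p = 4.8e-04), both with adjusted p = 0.0785 with an estimated correlation. The naive genes were lower (−0.74, 13 called, 18 adjusted over the list alone, adjusted p = 0.232 with an estimated correlation), and so were the effector genes (−0.44, 6 called, 7 adjusted over the list alone, adjusted p = 0.285 with an estimated correlation). Lower as well were the common gamma chain genes (−0.04, 6 called, 7 adjusted over the list alone) and CD8 markers (−0.36, 7 called, 11 adjusted over the list alone), both with adjusted p = 0.202 with an estimated correlation. Higher were the S phase (0.30, 1 called, 1 adjusted over the list alone) and MYC genes (0.21, 2 called, 3 adjusted over the list alone), both with adjusted p = 0.629 with an estimated correlation. The heat shock genes were higher too (0.28, 1 called, 1 adjusted over the list alone, adjusted p = 0.232 with an estimated correlation). These counts are of members in the direction of the list. In the order IL-2, memory, naive, effector, common gamma chain, CD8, dendritic cell and gamma delta, 1, 1, 1, 2, 2, 2, 1 and 1 members were called higher in wild type (1, 3, 3, 4, 2, 3, 1 and 1 adjusted over the list alone). Among them were Zbtb46 (1.77 ± 0.48, SE), Xcl1 (0.81 ± 0.17), Cd6 (0.55 ± 0.09) and Jak2 (0.51 ± 0.10). Against untreated set B alone the S phase and MYC medians turned to −0.13 and −0.10. That comparison also ended the calls of the naive genes (−0.12), CD8 markers (−0.12) and common gamma chain genes (0.01, a call also lost without any one of 4 libraries), and the effector genes were not called against set C alone or without untreated replicate 5.

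In the knockout the type I interferon genes (−0.59, 14 called, 23 adjusted over the list alone) were lower with anti-IL-2. So were the common gamma chain genes (−0.09, 7 called, 8 adjusted over the list alone), memory genes (−0.53, 6 called, 11 adjusted over the list alone), dendritic cell markers (−0.74, 1 called, 4 adjusted over the list alone) and gamma delta markers (−1.59, 3 called, 5 adjusted over the list alone), and each of the 5 lists had adjusted p = 0.0735 with an estimated correlation. Effector genes (−0.55, 7 called, 11 adjusted over the list alone) and CD4 and regulatory T cell markers (−0.34, 1 called, 2 adjusted over the list alone) were lower, both with adjusted p = 0.1195 with an estimated correlation. The naive genes (−0.60, 5 called, 12 adjusted over the list alone, adjusted p = 0.486 with an estimated correlation) and TCR immediate early genes (−0.16, 5 called, 10 adjusted over the list alone, adjusted p = 0.593 with an estimated correlation) were lower. The CD8 markers were lower (−0.30, 4 called, 9 adjusted over the list alone, adjusted p = 0.296 with an estimated correlation) and the S phase genes higher (0.27, 0 called by edgeR, adjusted p = 0.7101 with an estimated correlation). Called higher in the knockout, against the direction of their list, were 2 common gamma chain genes, among them Jak2 (0.64 ± 0.10), 2 CD8 markers, among them Cd6 (0.44 ± 0.09), and 1 each of the IL-2, TCR immediate early, effector, memory, naive and gamma delta lists. Adjusted over the list alone these were 2, 3, 2, 4, 2, 1, 3 and 1. Against untreated set B alone the common gamma chain, naive (−0.24), CD8, dendritic cell (−0.36), gamma delta (−1.003), TCR immediate early and S phase (0.05) lists lost their calls in the knockout. Single libraries ended those of the TCR immediate early, S phase and CD4 lists. The median of the G2 and M phase genes depended on the untreated set, at −0.86 against set B and 0.63 against set C in wild type, and −0.68 and 0.32 in the knockout.

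The genotypes' responses to anti-IL-2 were compared as an interaction, where the library set cancels in the estimate if it acts alike on both. The response of Cish differed by −1.13 ± 0.56 (SE) log2 units (−0.34 against untreated set B, −2.28 against set C) and that of Gzmb by −1.11 ± 0.92 (0.03 and −2.65). That of Ifng differed by −1.56 ± 0.95 and of Bcl2 by −0.65 ± 0.22, and all 4 had an adjusted p of 1. Il2ra (−0.59), Socs2 (−1.27), Eomes (−0.61), Myc (−0.22), Socs3 (−0.14), Socs1 (0.04), Tbx21 (0.11), Sh2b3 (0.43) and Il2 (0.72) did not pass either. edgeR called 0 genes (650 at an unadjusted p under 0.05), DESeq2 1, and edgeR against untreated set C alone 16. The full fit had no set term, so spread between sets B and C can hide calls. As lists the response of the knockout lay below that of wild type for the IL-2 and STAT5 targets (median −0.30, 1 adjusted over the list alone, adjusted p = 1.7e-04) and TCR immediate early genes (−0.21, adjusted p = 6.4e-04). The same held for the heat shock genes (−0.15, 1 adjusted over the list alone, adjusted p = 0.0146) and ATF4 targets (−0.18, adjusted p = 0.036), and each of the 4 had adjusted p = 0.643 with an estimated correlation. It also lay below for the MYC genes (−0.20, 1 adjusted over the list alone, adjusted p = 5.4e-05) and above for the RNA quality genes (0.46, adjusted p = 0.0235), both with adjusted p = 0.715 with an estimated correlation. None of these 6 lists was called against untreated set B alone. Further settings ended the calls of the ATF4, RNA quality and heat shock lists, called in 13, 14 and 19 of 22.

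The time course in wild type gives the background of stimulation, culture and time since isolation together. No group was cultured without stimulation, so these cannot be told apart in the changes against 0 h. At 2 h against 0 h the activation genes Nr4a3, Irf4 and Il2ra rose by 6.28 ± 0.46, 5.49 ± 0.37 and 4.65 ± 0.39 (SE) log2 units (adjusted p = 1.8e-11, 2.8e-12 and 1.4e-10), and Cish by 2.91 ± 0.51 (adjusted p = 2.4e-05). At 6 h Xcl1, Ccl3 and Pdcd1 were 10.66 ± 0.74, 7.89 ± 0.61 and 5.94 ± 0.51 above 0 h, and at 24 h Gzmb, Il2ra and Tbx21 were 8.40 ± 0.67, 6.37 ± 0.33 and 3.50 ± 0.27 above it. Falls included Bcl2 at 2 h (−1.23 ± 0.10), Cd8a (−1.70 ± 0.08 at 2 h), Mx1 (−4.88 ± 0.26 at 2 h) and Igfbp4 (−5.61 ± 0.31 at 6 h). In all, 3906 genes rose and 4020 fell at 2 h among 14593 tested, 3679 and 3614 at 6 h, and 4016 and 3826 at 24 h among 14427.

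The other named changes at 2 h were the rises of Il2 (7.94), Mir155hg (7.57), Mpzl1 (6.87), Tnfsf11 (6.87), Tbx21 (2.30) and Myc (1.12) and the falls of Hspa1a (−7.03), Hspa1b (−6.84), Zfp683 (−5.79), Jun (−5.49) and Socs3 (−2.33). Not called at 2 h were Socs1 (0.04), Gzmb (−0.12), Eomes (−0.62) and Ifng (−2.24). At 6 h Eml1 (10.21), Il2 (9.40), Bcat1 (8.81), Rgs16 (7.56), Tbx21 (2.32), Cish (1.80) and Myc (0.95) rose. Hspa1b (−8.37), Zfp683 (−6.86), Klf4 (−5.98), Socs3 (−3.06) and Bcl2 (−0.99) fell, with Gzmb (0.45), Socs1 (0.27), Eomes (−0.52) and Ifng (−1.08) not called. At 24 h Dnph1 (10.91), Ccl1 (10.78), Spin4 (10.51), Bcat1 (9.55), Ccl9 (8.91), Il2 (8.72), Socs2 (4.95), Ifng (3.65), Cish (2.99), Socs1 (1.54) and Myc (1.07) rose. Hspa1a (−6.79), Fos (−6.01), Slc16a5 (−5.65), Ggt1 (−5.56) and Socs3 (−2.67) fell. Sh2b3 (−0.24, adjusted p = 0.157) and Eomes (0.05) were not called at 24 h.

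At 24 h against 0 h the G2 and M phase genes had a median of 4.34 (29 called, 29 adjusted over the list alone) and the S phase genes 2.85 (30 and 30). The cholesterol genes had 0.89 (22 and 23 higher, 4 lower) and inhibitory receptors 1.36 (15 and 15 higher, 2 lower), and these 4 lists had adjusted p = 0.164 with an estimated correlation. The MYC genes had a median of 1.13 (32 and 32), glycolysis genes 0.61 (14 higher, 3 lower) and effector genes 0.98 (14 higher, 5 lower). The CD4 and regulatory T cell markers stood at 2.46 (7 higher, 1 lower) and the type I interferon genes at −1.76 (39 and 39 lower, 2 higher), and these 5 had adjusted p = 0.228 with an estimated correlation. The IL-2 and STAT5 targets (1.07, 21 higher, 6 lower, adjusted p = 0.334 with an estimated correlation) and ATF4 targets (1.08, 21 higher, 2 lower, adjusted p = 0.106 with an estimated correlation) were higher. So were the interferon gamma response (0.66, 17 higher, 6 lower, adjusted p = 0.539 with an estimated correlation) and TCR immediate early genes (1.36, 20 higher, 9 lower, 20 and 10 adjusted over the list alone, adjusted p = 0.467 with an estimated correlation). The naive genes (−0.76, 20 lower, 5 higher, 23 and 5 adjusted over the list alone, adjusted p = 0.468 with an estimated correlation) and CD8 markers (−0.68, 12 lower, 2 higher, adjusted p = 0.150 with an estimated correlation) were lower. At 2 h the type I interferon genes stood at −2.20 (47 of 50 lower, adjusted p = 0.179 with an estimated correlation) and at 6 h they stood at −2.27 (46 lower, adjusted p = 0.069 with an estimated correlation). The TCR immediate early genes stood at 1.99 at 2 h (20 higher and 7 lower, among them Junb at −2.90, adjusted p = 0.826 with an estimated correlation) and 1.71 at 6 h (19 higher and 10 lower, 20 and 10 adjusted over the list alone, adjusted p = 0.632 with an estimated correlation).

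Further lists at 2 h were the inhibitory receptors (1.09, 15 higher, 1 lower, adjusted p = 0.188 with an estimated correlation) and common gamma chain genes (0.68, 18 higher, 4 lower, adjusted p = 0.282 with an estimated correlation). The IL-2 and STAT5 targets were higher (0.81, 21 higher, 6 lower, 21 and 9 adjusted over the list alone, adjusted p = 0.742 with an estimated correlation), as were the apoptosis genes (0.69, 13 higher, 4 lower, 15 and 4 adjusted over the list alone, adjusted p = 0.107 with an estimated correlation). The p53 targets (0.70, 9 higher, 1 lower, adjusted p = 0.609 with an estimated correlation) were higher and the CD8 markers (−0.72, 10 lower, 2 higher, adjusted p = 0.0832 with an estimated correlation) lower. At 6 h the MYC genes (0.89, 30 of 32 higher) and ATF4 targets (0.96, 17 higher, 3 lower) had adjusted p = 0.529 with an estimated correlation. The p53 targets (1.39, 16 higher, 1 lower), inhibitory receptors (1.53, 17 higher, 2 lower, 18 and 2 adjusted over the list alone), apoptosis genes (0.81, 15 higher, 5 lower) and CD4 and regulatory T cell markers (0.99, 7 higher) had adjusted p = 0.069 with an estimated correlation. The CD8 markers were lower at 6 h (−0.83, 11 lower, 2 higher, adjusted p = 2.8e-06), a call that held with an estimated correlation (adjusted p = 0.0087). Where no second count is given, the count adjusted over the list alone was equal. Over time the heat shock list differed in sign at 24 h, with a median of 0.69, a mean of −0.06 and an upward test. The common gamma chain list had a median of −0.06, a mean of 0.50 and an upward test, and neither was called.

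Whether the genotype difference changed with time was tested as an interaction against 0 h. The fits used set A for 2 and 6 h and sets B and C for 24 h. At 24 h the difference shifted by 1.46 ± 0.46 (SE) log2 units for Cish (0.09 in set B, 2.55 in set C, adjusted p = 0.369) and 2.04 ± 1.16 for Gzmb (adjusted p = 0.676). It shifted by 2.32 ± 0.94 for Ifng (adjusted p = 0.534), 1.11 ± 0.43 for Il2ra (adjusted p = 0.511) and 0.63 ± 0.19 for Bcl2 (adjusted p = 0.353). Socs2 (3.09), Eomes (1.01), Tbx21 (0.28), Myc (0.21), Socs3 (0.12), Socs1 (0.06) and Il2 (−1.01) were not called. At 6 h Ifng (2.56), Gzmb (1.58), Il2ra (1.06) and Cish (0.94) had adjusted p = 1, and at 2 h Il2ra (0.54), Socs3 (0.53) and Ifng (0.37) had adjusted p = 0.995. edgeR called 0 genes at 2, 6 and 24 h, with 722, 635 and 1211 at an unadjusted p under 0.05, and DESeq2 called 0, 0 and 20. The change in Sh2b3 itself was −0.51, −0.22 and 0.16.

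As lists at 24 h the difference shifted upward for the IL-2 and STAT5 targets (median 0.31, 5 adjusted over the list alone, adjusted p = 3.9e-06) and effector genes (0.38, 6 adjusted over the list alone), both with adjusted p = 0.336 with an estimated correlation. It did so for the cholesterol genes (0.36, 6 adjusted over the list alone), glycolysis genes (0.29, 3 adjusted over the list alone) and ATF4 targets (0.15). It shifted downward for the type I interferon genes (−0.44, 3 adjusted over the list alone, adjusted p = 3.7e-12), and these 4 lists too had adjusted p = 0.336 with an estimated correlation. It shifted upward for the MYC genes (0.29, 3 adjusted over the list alone), TCR immediate early genes (0.28, 2 adjusted over the list alone) and heat shock genes (0.25, 2 adjusted over the list alone). It shifted downward for the B cell markers (−0.51), and these 4 had adjusted p = 0.475 with an estimated correlation. The naive genes (−0.16, adjusted p = 0.541 with an estimated correlation) and interferon gamma response (−0.04, adjusted p = 0.711 with an estimated correlation) also shifted downward. At 6 h the interferon gamma response shifted upward (0.66, 23 adjusted over the list alone, adjusted p = 3.6e-16, adjusted p = 0.542 with an estimated correlation). The type I interferon (0.40) and common gamma chain genes (0.13) did so too, while the inhibitory receptors (−0.22), S phase genes (−0.08) and p53 targets (−0.15, 3 adjusted over the list alone) shifted downward, these 5 with adjusted p = 0.595 with an estimated correlation. The MYC genes shifted downward at 6 h (−0.07, adjusted p = 0.993 with an estimated correlation) and 2 h (−0.15), where the cholesterol genes shifted upward (0.26), both with adjusted p = 0.997 with an estimated correlation.

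Across the 5 genotype comparisons Sh2b3 and Gm6472 were called in every one and Id2, Rnf157, Adi1, Rps7 and Trappc12 in 3. The calls at 24 h and at 24 h with anti-IL-2 shared 8 higher genes, among them Id2, Igtp, Iigp1, Ppic and Rnf157, and 4 lower genes, Sh2b3, Id3, Rps7 and Trappc12. Sh2b3 is shared by design, and Id2, Adi1, Rps7 and Trappc12 lie together on chromosome 12, so these are not independent draws. Without Sh2b3, Gm6472 and the whole chromosome 12 region in which calls cluster at 0 h, at 24 h or with anti-IL-2, a test chosen after the overlap was seen, 5 higher genes stayed shared, against 0.0498 given by chance if genes were independent (hypergeometric adjusted p = 2.1e-08). Igtp and Iigp1 among them belong to the interferon gamma response list, so they are not independent draws, and this p can be too small. Of the lower genes Id3 alone stayed, against 0.0156 (adjusted p = 0.0621). Left out in the same way, the calls at 0 and 24 h shared Rnf157 (adjusted p = 0.210) and no lower gene. Those at 0 h and at 24 h with anti-IL-2 shared Mid1 and Rnf157 (adjusted p = 0.0189) and the lower Tmem181b-ps (adjusted p = 0.118). The comparisons share no libraries but may share animals, so these p can be too small.

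Some recurring genes lie together on chromosome 12. At 0 h Odc1, Id2, Adi1 and Tmem18 were higher (0.27 ± 0.06, 0.68 ± 0.14, 0.78 ± 0.10 and 0.46 log2 units) and Ywhaq, Rnf144a, Rps7 and Trappc12 lower (−0.32, −1.79 ± 0.31, −0.33 and −0.43), all called. At 24 h the 5 called were Id2, Adi1 (0.65), Rps7 (−0.48, adjusted p = 0.047), Trappc12 (−0.65) and Hpcal1 (−0.56). With anti-IL-2 the 7 called were Id2, Adi1 (0.56), Rps7 (−0.46), Trappc12 (−0.51), Kidins220 (−0.47), the pseudogene Gm10478 and Acp1, which was also called lower at 0 h. Permutation p for so many in 30 neighbouring tested genes was 5e-04 at 24 h and 1e-04 with anti-IL-2. Rps7 was at 2408 ± 299.8 CPM (SD, n = 11) in wild type and 1917 ± 329 CPM in the knockout at 0 h. Gm6472 (ENSMUSG00000095597), which the rule leaves out and which was chosen after its values were seen, went from 11.8 ± 3.21 to 330.4 ± 127 CPM at 0 h. At 24 h it went from 10.6 ± 2.52 to 181 ± 35.4 CPM, and its log2 differences were 4.83 and 4.05. Its name is that of a predicted gene or pseudogene, and reads shared with a parent gene were not separated.

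**Figure D3:**
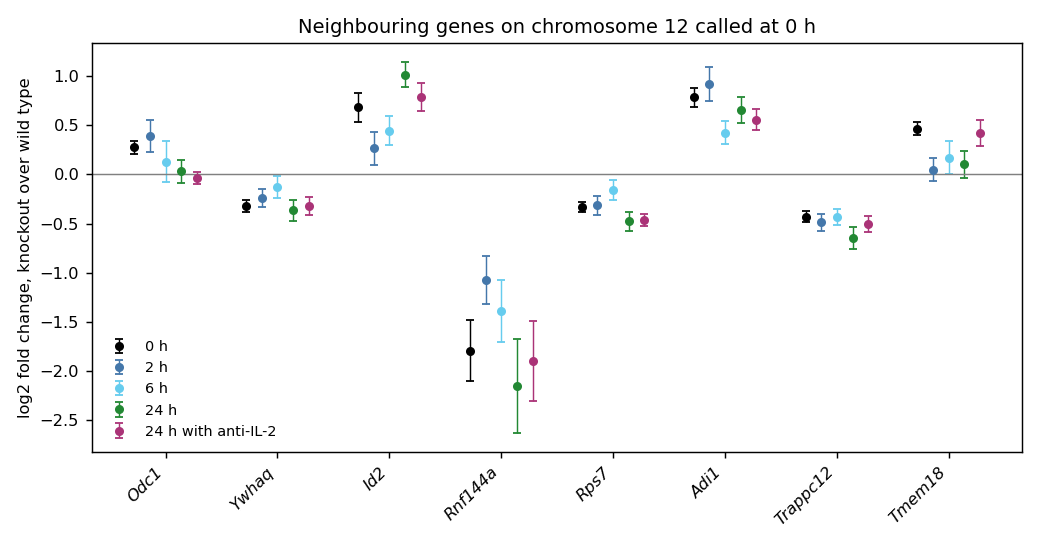
Log2 difference between knockout and wild type ± SE (vertical axis) of 8 genes of a chromosome 12 region in the 5 genotype comparisons (colours), genes in chromosome order (horizontal axis). Id2 and Adi1 lie above 0 in every comparison, at 0.68 and 0.78 at 0 h, and Rnf144a, Rps7 and Trappc12 below it.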

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

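The tests of a shared animal, of a mislabelled library and of the weight of 1 library in the interferon gamma list were chosen only after the result was seen, and the test for cells of another type was planned. A library is listed here when it lay far from the others of its group of 4 to 10, by its gap to the nearest library as a share of the range of the group, under a rule that chance alone meets in about 1 in 20 groups. Of 160 groups of values examined, 20 met it, against 8 given by chance.

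Knockout replicate 3 at 6 h lay above its group in Cish (81.1 CPM, next 18.4), Ifng (64.7 CPM), Tbx21 (222 CPM, next 35.2), Il2 (23.0 CPM), Gzmb (7.93 CPM) and Lta (108.6 CPM). Knockout replicate 3 at 2 h lay above its group in Tbx21 (149.6 CPM, next 22.0), Socs3 (125.0 CPM, next 80.1) and Ifng (3.90 CPM). Eomes was low in knockout replicate 5 at 2 h (11.1 CPM, next 30.6). Further libraries apart were knockout replicate 4 at 24 h in Ifng (299.9 CPM, next 102.9), wild-type replicate 3 at 24 h in Socs3 (38.2 CPM), wild-type replicate 4 at 6 h in Tbx21 (24.8 CPM) and wild-type replicate 1 at 6 h in Socs2 (0.306 CPM, the others at 0). For genes on the pseudogene question they were wild-type replicate 4 at 2 h in Rps7 (2717 CPM), knockout replicate 4 at 2 h and at 6 h in Gm6472 (377 and 319 CPM) and knockout replicate 1 at 24 h in Gm9493 (4.82 CPM). Total counts were high in wild-type replicate 5 (26.5 M reads) and knockout replicate 1 (35.5 M reads) at 24 h.

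Knockout replicate 10 at 0 h, replicate 3 at 2 h and replicate 3 at 6 h stood apart from the other knockout libraries in the same genes, with Mmp14 5.87, 6.16 and 5.84 log2 units above them. A swap with wild type is argued against by Sh2b3, whose level in these libraries was at most 0.248 of the lowest wild-type library of the time. Their library numbers are 10 apart, and their deviations correlated with r of 0.342 to 0.554 across genes, which are not independent, and in the other 27 libraries of set A those 10 apart also correlated more (mean r of 0.0698) than others (−0.0196, permutation p = 1e-04, the smallest they can give), though only 5 of 27 pairs were over 0.1 and the lowest was at −0.0223, so 1 animal may have supplied the 3 libraries. Cells of another type, which negative selection is meant to remove, cannot be told apart from this, since the markers of gamma delta T cells, 1 of 8 marker lists, were highest in them at all 3 times, while Cd8a was lowest at 0 h only (at 6 h 9.10 log2 CPM, highest other 8.998) and Cd3e at 6 h only (at 0 h 9.31, highest other 9.29), levels too high to show a small share of other cells, and no biological explanation was tested. Without knockout replicate 3 the interferon gamma list at 6 h kept a median of 0.43 of 0.81, so that library may carry part of the difference but not all of it.

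The difference between the genotypes itself differed between conditions for some lists, by tests of the interaction. With camera at the preset correlation 6 lists were called for anti-IL-2, and 2, 7 and 12 for time at 2, 6 and 24 h against 0 h. With an estimated correlation 0 were called in each.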

How the results depend on the processing

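All alternatives reported here were chosen before the data were examined except the settings without knockout replicate 10 at 0 h, without the 3 knockout libraries that stand apart, and with a replicate block, which were chosen after the result was seen. For single genes of the naming rule, without uncalled list members and over all 14 comparisons, 7788 of 8620 values kept direction and side of the threshold. Of the others 683 lost the call, 71 gained one and 78 changed sign, none of the latter with a call under the alternative. The genotype comparisons were less stable than this total. For genotype at 24 h 386 of 612 values stayed, 187 lost the call, 34 gained one and 5 changed sign. At 0 h 231 of 314 stayed and 65 lost the call. Sh2b3 kept its direction and its call in the 5 genotype comparisons under every alternative run. Where no cause is named, the cause was not tested.

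The number of called genes depended on the test. For genotype at 0 h (81 calls) DESeq2 called 165, no filter on low counts 477, no library set term 28, library set A alone 6, a change of 1.5-fold or more 32, and the fit without knockout replicate 10 called 137. For genotype at 2 h (8 calls) DESeq2 called 122, limma voom 76, no filter 230 and DESeq2 size factors 4, and leaving out 1 library gave 3 to 63. For genotype at 6 h (4 calls) DESeq2 called 28 and limma voom 11, and leaving out 1 library gave 3 to 5. For genotype at 24 h (48 calls) DESeq2 called 231, limma voom 944, no filter 362, no library set term 3 and library set B alone 11, and leaving out 1 library gave 8 to 361. For genotype at 24 h with anti-IL-2 (47 calls) DESeq2 called 141, limma voom 113, no filter 191 and 1.5-fold or more 18, and leaving out 1 library gave 10 to 76. A set alone and a minimum change leave fewer libraries or genes by construction.

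For anti-IL-2 in wild type (877 calls) DESeq2 called 1432 and the comparison with untreated set C alone 3511, and leaving out 1 library gave 384 to 1325. For anti-IL-2 in knockout (832 calls) DESeq2 called 1270, untreated set B alone 1575 and set C alone 2155, and leaving out 1 library gave 446 to 946. The interaction of genotype with anti-IL-2 (0 calls by edgeR) had 1 with DESeq2, 16 against set C alone and 0 in all 18 fits without 1 library. That of genotype with time at 24 h (0 calls by edgeR) had 20 with DESeq2 and 141 with no filter. Leaving out 1 library gave 7492 to 7690, 6880 to 7149 and 7384 to 7835 calls at 2, 6 and 24 h against 0 h. At 6 h 2302 rises and 2267 falls reached 1.5-fold.

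The labels pair no libraries. With library numbers 10 apart as a replicate block, 8353 genes were called at 2 h against 0 h (7926 without it) and 7668 at 6 h (7293 without it), 7832 and 7166 of them the same genes in the same direction. The interactions of genotype with time at 2 and 6 h kept 0 calls with the block, with 973 and 854 at an unadjusted p under 0.05. Tbx21 changed sign in both, to −0.35 and −0.15 with the block and −0.65 and −0.52 without the 3 knockout libraries that stand apart, as did Gzmb at 2 h (−0.0088) and Eomes at 6 h (−0.14) without them.

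Most list calls rest on the preset correlation. With an estimated correlation the called lists went from 8, 3, 10, 15 and 8 to 0 in the genotype comparisons at 0, 2, 6, 24 h and 24 h with anti-IL-2, from 13 to 4 and 13 to 2 for anti-IL-2 in wild type and knockout, from 8, 9 and 15 to 0, 1 and 0 at 2, 6 and 24 h against 0 h, and from 6, 2, 7 and 12 to 0 for the interactions with anti-IL-2 and with time at 2, 6 and 24 h. By fry, which compares no list with other genes, they were 1, 1, 0, 4 and 4 in the genotype comparisons, 15, 23 and 25 against 0 h, and 0 in the 4 interactions.

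Genes that changed sign under an alternative were uncalled in both settings unless stated. In genotype at 0 h they were Cish (−0.15 with limma voom, −0.24 in set C, −0.15 without knockout replicate 10), Bcl2 (−0.00096 with limma voom, −0.075 in set C), Gzmb (−0.25 in set A), and in set B Ifng (−0.82), Myc (−0.38) and Odc1 (−0.080, called in the full fit). In genotype at 24 h they were Il2 (−0.071 with limma voom, −0.76 in set B) and in set B Il2ra (−0.016) and Myc (−0.041). In genotype at 2 h Cish (−0.0025) and in genotype at 6 h Il2 (−1.04) and Myc (−0.025) changed sign with limma voom. For anti-IL-2 in wild type Eomes (0.41) and Myc (−0.27) did so against untreated set B and Il2 (0.22) and Il2ra (0.0087) against set C. In the interaction with anti-IL-2, Myc (0.039) did so against set B and Tbx21 (−0.51), Socs1 (−0.068) and Il2 (−0.082) against set C.

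Leaving out 1 library changed the sign of uncalled genes. At 2 h the ranges were −0.10 to 0.42 for Cish (lowest without knockout replicate 3), −0.31 to 0.056 for Eomes, −0.59 to 0.13 for Gzmb, −0.44 to 0.10 for Il2 and −0.17 to 0.19 for Myc. At 6 h they were −0.084 to 0.024 for Bcl2, −0.0069 to 0.55 for Eomes (lowest without knockout replicate 3), −0.77 to 0.78 for Il2 and −0.22 to 0.19 for Myc. At 24 h the range was −0.055 to 0.58 for Il2, and with anti-IL-2 they were −0.16 to 0.25 for Cish, −0.027 to 0.052 for Myc, −0.47 to 0.59 for Socs2 and −0.061 to 0.34 for Socs3. For anti-IL-2 in wild type Myc ran from −0.031 to 0.11. In the interaction with anti-IL-2 Socs1 ran from −0.044 to 0.14, Socs3 from −0.42 to 0.024 and Tbx21 from −0.17 to 0.32. Against 0 h in wild type Gzmb ran from −0.29 to 0.11 and Socs1 from −0.11 to 0.20 at 2 h, and Eomes from −0.059 to 0.18 at 24 h.

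At 13987029 counts or more per library, depth limits genes near the floor, such as Il2 and Socs2, which the filter on low counts left out of the comparison of genotypes at 0 h. A planned sex term was not run, since all 60 libraries are of 1 sex, and the voom fit was planned for genotype comparisons only.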

Other observations

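The tests on chromosome 12 and on Gm6472 were chosen only after the result was seen, and the regrouping of samples was planned.

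Of the genes called at 0 h, 10 lie within a stretch of 30 tested genes on chromosome 12, among them Odc1, Ywhaq, Id2, Rnf144a, Rps7, Adi1, Trappc12 and Tmem18. Chance placement of the calls gave at most 5 in any such stretch over 10000 permutations (p = 1e-04, the smallest they can give). Stretches were searched within each comparison, so neighbouring genes called at different times were not looked for. A candidate explanation is a chromosome segment that differs between the mice of the genotypes: with anti-IL-2 at 24 h, in other libraries, 7 of the 8 tested genes kept their direction (one-sided exact binomial p = 0.0352), with Odc1 the exception. The segment around the targeted gene cannot be the source of these calls, since that gene lies on chromosome 5, where 1 of its 27 tested neighbours (Atxn2) was called. An effect of the loss of Sh2b3 on these genes cannot be told apart from such a segment, since every knockout library may carry both; 1 of the 10 genes, Id2, differed in its genotype effect between 0 and 24 h (by 0.50 log2 units, adjusted p = 0.0253 over these genes).

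Gm6472 was higher and Rps7 lower in the knockout in all 5 genotype comparisons. Reads of Rps7 counted for its processed pseudogenes could link them: the log2 difference of the sum of Rps7 and its pseudogenes had 0.333 to 0.527 of the size of that of Rps7 alone, with the opposite sign at 6 h (0.05 against −0.13), but adding a gene that is higher to one that is lower shrinks the difference whatever its source. Gm9493, the other pseudogene in the sum, was lower in the knockout (−1.42 log2 units at 0 h, adjusted p = 1.4e-06, and −1.67 at 24 h, adjusted p = 0.0529), against a move of reads to it. Since the counts cannot be reassigned to their reads, this cannot be told apart from a difference in both. A higher transcription of the pseudogene alone leaves the lower Rps7, called in 3 of the 5 comparisons and itself part of the pattern, unaccounted for. Rps7 also lies in the chromosome 12 stretch above, so the candidate segment could bear on its fall apart from Gm6472.

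Other splits of the same samples were refitted to see whether chance can be excluded for each count of calls. For genotype at 0 h, 1 of 100 splits, the real one, gave as many (81 calls, highest other 0). For genotype at 24 h 1 of 60 did (48, highest other 10), and with anti-IL-2 1 of 35 (47, highest other 0). For genotype at 2 h 2 of 100 splits gave as many (8, highest other 227) and at 6 h 2 of 100 (4, highest other 1515). In all 5 genotype comparisons the real labels call Sh2b3 by design, and the median of the other splits was 0. Such a share therefore cannot exclude chance for the calls beside Sh2b3. Sh2b3 and Gm6472 were 2 of the 4 calls at 6 h. The splits with several times the real count point to a structure of the samples. At 2 h the highest split grouped knockout replicate 3 with wild-type replicates 1 to 4. At 6 h it grouped knockout replicates 2 and 3 with wild-type replicates 3 to 5. For anti-IL-2 in wild type 4 of 100 splits gave as many (877, highest other 1332), and the highest one parted untreated set B from set C, so the library sets are such a structure. Against set B alone 932 genes were called and against set C alone 3511. In the knockout 1 of 100 did (832, highest other 519). For 2, 6 and 24 h against 0 h 1 of 100 splits each gave as many (7926, 7293 and 7842, with highest others of 3454, 3085 and 6341), so chance can be excluded. With 0 calls in each interaction all 100 splits give as many by definition, so they say nothing about chance. The highest others were 0 for anti-IL-2 and 0, 1173 and 6 for time at 2, 6 and 24 h, and the 1173 again points to a structure of the samples.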
